A study of Mus musculus with 2 samples.

How the data were processed

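Cells sorted as CD45-positive and JAML-positive from mouse tumours were measured by droplet single-cell RNA sequencing. The 2 GEO samples were the gene expression library and the antibody-tag (CITE) library of the same sort, made with 10x Genomics 5' v2 chemistry per the labels. Per the submitters' processing notes, reads were processed with Cell Ranger 3.1.0 against the mm10 genome and with Seurat 3.1.5. The deposited gene expression matrix holds counts of unique molecular identifiers (UMIs), with no normalization, for 15416 genes and 5976 cells. The deposited annotation gives for each cell its total UMI counts, its number of genes, the percent of its UMIs from mitochondrially encoded genes, a hashtag, cluster numbers and the authors' cluster name, which is a marker gene in brackets. In all 5976 cells the annotated UMI total and gene number equalled those of the matrix. The filters behind the matrix were not stated in words. Its values lie between 1499 and 5999 genes per cell and at or under 5% mitochondrial UMIs, and every gene has UMIs in at least 6 cells. The table of hashtag names and sequences holds no measurement and was not used further.

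The hashtags assign 5968 cells to 3 mice, and 8 cells with no hashtag were left out of values per mouse. There is one experimental group, so every comparison was made between classes of cells within the same 3 mice. Classes were the authors' 6 clusters at resolution 0.1 and 16 subclusters at resolution 0.8, given cell type names with the suffix "-like" from marker lists. Lineage gates used transcripts. A CD8-gate cell had at least 1 UMI of Cd8a or Cd8b1 and of Cd3d, Cd3e or Cd3g, and none of Cd4. A CD4-gate cell had Cd4 and Cd3 UMIs and none of Cd8a or Cd8b1. The gates, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The restriction to the Cd3g and Pdcd1 clusters, called the T-cell clusters here, and the comparisons inside single clusters were added after the data were seen. Foxp3 has no row in the matrix, so the comparison of regulatory with conventional CD4 cells could not be run.

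UMI counts were summed per mouse and class, and classes of a mouse with under 10 cells were left out. Paired classes were compared with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, the mouse as a block) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are log2 with the standard error of the fitted coefficient. Levels are CPM (a class's UMI counts scaled to a fixed total) as means over 3 mice with the SD. For cells with against without a UMI of Itgae or of Jaml, the classes were brought to equal numbers within each decile of total UMIs in each mouse, by drawing with a fixed seed from the larger class. Gate genes were left out of counts and names. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation and fry, with adjustment over the lists. DESeq2 1.42.0 was an alternative. Shares have exact Clopper-Pearson 95% intervals. A count of 0 allows up to 3 UMIs, taken over the group. Intervals and floors cover counting error only. Differences of a list between groups of subclusters are means over its members of log2 of CPM plus 1. For shares of cells with a UMI, every cell was also thinned to 7537 UMIs, the 10th percentile, and shallower cells were left out.

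The text names, for each gene comparison, the 8 genes with the largest fold change per direction past the threshold, with at least 30 CPM in the higher class and the same direction in every mouse. It adds the 3 members with the smallest adjusted p of each list that camera called, up to 12 genes. A fixed set of Jaml, Cxadr, Itgae, Pdcd1, Havcr2, Tcf7, Cxcr6, Gzmb, Foxp3 and Cd69 completes it. Receptor segments, mitochondrial and ribosomal protein genes and unnamed gene models were left out of the first parts. From these genes the ones printed with values were picked. For clusters it takes the 5 genes with the largest fold over the other clusters among genes with UMIs in at least 25% of the cluster's cells.

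Alternatives were RLE size factors, no filter on low counts, DESeq2, no mouse block, a threshold of 0.01, each mouse left out, a gate at 2 UMIs, unmatched cells, thinned cells (gated again and not matched), another matching draw, a stricter cell filter (1000 UMIs, 500 genes, under 5% mitochondrial) and removal of T-gate cells with at least 2 UMIs of Cd79a, Lyz2 or C1qa together with Scrublet calls. For Itgae or Jaml, the gate at 2 UMIs took cells with at least 2 UMIs of that gene against cells with none. The lineage gate stayed as it was. For CD8 against CD4, it asked CD8-gate cells for at least 2 UMIs of Cd8a and Cd8b1 together and left the CD4 gate unchanged. Scrublet called 8 of the 5976 cells (0.134%), too few to take as a working call. Clusters were rebuilt with scanpy 1.11.5 and leidenalg 0.10.2 from 2000 variable genes, 30 principal components and 15 neighbours. Gene positions come from GENCODE M21, where 15250 symbols of the matrix were found. Other code used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

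The test was tested on simulated data with planted changes in 200 genes, in 5 simulations per comparison. The 200 genes were drawn only from genes with enough expected UMIs in both classes. These were 2677 of 9501 genes for CD8 against CD4 cells, 5131 of 5292 for Itgae and 9360 of 9478 for Jaml. Recovery among the other genes was not measured. Of planted 2-fold changes the test recovered 30% for CD8 against CD4 cells of the T-cell clusters, 55.8% for cells with against without Itgae UMIs there, and 83.2% for cells with against without Jaml UMIs. Of planted 1.5-fold changes it recovered 4.6%, 15.6% and 57.2%. False calls made up 9.43%, 8.53% and 5.58% of the calls.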

Results

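Single-cell transcriptomes were collected from CD45-positive, JAML-positive cells sorted from mouse tumours, in a series about JAML as a target on tissue-resident memory T cells. JAML (junction adhesion molecule-like) is a surface receptor whose ligand is the adhesion protein encoded by Cxadr, and it can costimulate T cells. The labels call the sorted cells T cells, while the extraction label also uses the word TREG. The matrix held 5976 cells and 103155608 UMIs, with a median of 14439 UMIs (range 2953 to 49843) and 3473 genes per cell. Mouse 1 gave 2445 cells and 48047914 UMIs, mouse 2 gave 1184 cells and 22004939 UMIs, and mouse 3 gave 2339 cells and 33009303 UMIs. Their medians were 16912, 15917 and 11648 UMIs per cell. All 3 mice belong to 1 group, so the spread between mice is the only replicate error and no treated or control group was compared. In mm10, Jaml lies on chromosome 9 from 45079183 to 45108534, and Itgae, which encodes the residency integrin CD103, lies on chromosome 11 from 73090583 to 73147446. Unless stated otherwise, a gene given as higher or lower below was so in 3 of 3 mice.

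The sorted cells were a mixture in which T cell-like and dendritic cell-like cells were prominent, and 5 of the authors' 6 clusters are described here. The authors' Cd3g and Pdcd1 clusters carried T cell transcripts and together held 2801 cells, 46.9% of all cells (95% interval 45.6 to 48.1%; mean over mice 46.1 ± 7.92%, SD, n = 3). Dendritic cell-like clusters held 41.2%. Among them the Siglech cluster was plasmacytoid dendritic cell-like, led by Ly6d (122-fold over the other clusters), Siglech (116-fold), Cox6a2, Klk1 and Ccr9. The Xcr1 cluster resembled conventional type 1 dendritic cells, which cross-present antigen, and was led by Xcr1 (133-fold), Gcsam, Itgae (48.7-fold), Snx22 and Tlr3. The Ifitm1 cluster was led by Ffar2, Ifitm1, Ramp3, Cd209a (18.1-fold) and Ccr7, and its subcluster 4 resembled conventional type 2 dendritic cells.

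Shares of the pooled cells were 32.5% for the Cd3g cluster (95% interval 31.4 to 33.8%), 22.0% for Siglech (20.99 to 23.1%), 14.3% for Pdcd1 (13.4 to 15.2%), 11.6% for Ifitm1 (10.8 to 12.4%) and 7.53% for Xcr1 (6.87 to 8.23%). The mice differed most in the T cell-like clusters. The Cd3g cluster made up 18.7 to 49.0% of a mouse's cells and the Pdcd1 cluster 6.24 to 22.5%, while the Xcr1 share was 7.52 ± 0.00475% (SD, n = 3). Within the Cd3g cluster, 632 cells of subcluster 3 resembled natural killer cells or type 1 innate lymphoid cells, led by the receptor genes Klrb1c (70.0-fold), Klra1 (66.6-fold), Klra7, Ncr1 and Klra6. The naming rule was met by 4 of 9 markers of these cells and by 3 of 9 gamma-delta T cell markers (Trdc, Tcrg-C2 and Tcrg-C4). Trdc was 35.8-fold higher and found in 28.0% of the cells, so the name does not exclude gamma-delta T cells. Cd3d and Trbc2 also met the rule. By transcript gates, 43.1% of all cells fell in the CD8 gate, 2.59% in the CD4 gate and 54.3% in neither. Inside the T-cell clusters, 2152 cells (76.8%) passed the CD8 gate and 59 (2.11%) the CD4 gate. Foxp3, the lineage factor of regulatory T cells, had no row, so the regulatory share could not be measured.

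**Figure D1:**
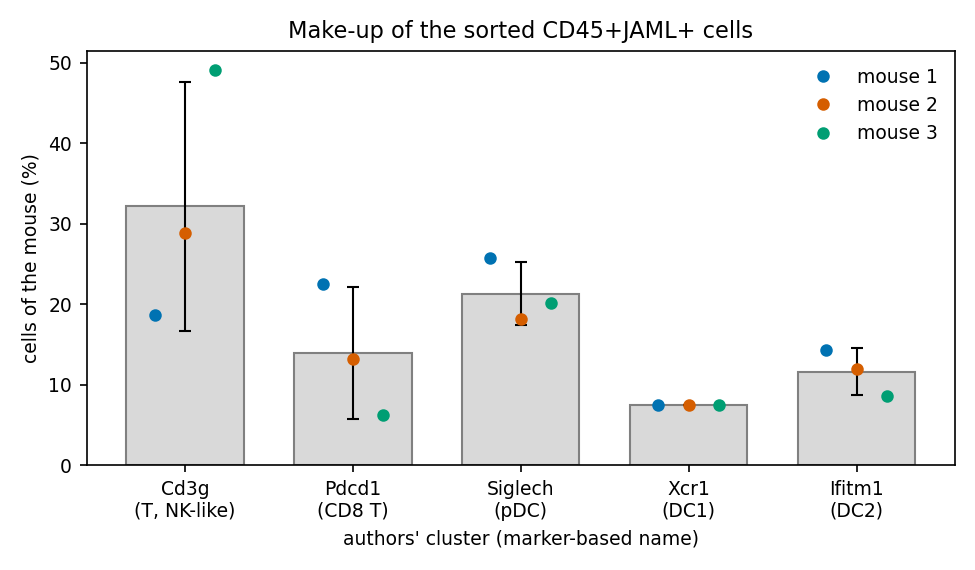
Percent of each mouse's cells (y axis) in 5 of the authors' 6 clusters (x axis, with a marker-based name); points are mice, bars the mean and error bars the SD (n = 3). The Cd3g cluster spans 18.7 to 49.0%, and the 3 mice nearly coincide in the Xcr1 cluster.

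Among these 5 clusters, Jaml RNA was highest in the Siglech and Xcr1 clusters. It reached 477 ± 30.3 CPM (SD, n = 3) in the plasmacytoid Siglech cluster, 353 ± 41.4 in the Xcr1 cluster and 222 ± 25.1 in the Ifitm1 cluster. The Cd3g cluster had 198 ± 6.07 CPM and the Pdcd1 cluster 81.2 ± 10.0. Against the average of the Cd3g and Pdcd1 clusters, Jaml was higher in the Siglech cluster by 1.84 ± 0.08 on the log2 scale (SE, adjusted p = 6.6e-12), in the Xcr1 cluster by 1.68 ± 0.08 (3.1e-11) and in the Ifitm1 cluster by 0.98 ± 0.08 (3.1e-08). It was also higher in the Cd3g than in the Pdcd1 cluster by 1.30 ± 0.10 (1.4e-07). Subclusters did not all follow their cluster: subcluster 15 of the Cd3g cluster had 651 ± 102 CPM in the 2 mice with at least 10 cells, and subcluster 12 of the Ifitm1 cluster had 159 ± 24.7. With every cell thinned to 7537 UMIs, a Jaml UMI was found in 93.9% of Siglech, 89.2% of Xcr1, 70.2% of Ifitm1, 64.2% of Cd3g and 40.8% of Pdcd1 cells. As background, Siglech UMIs, a plasmacytoid marker, were found at the same depth in 3.88 to 6.28% of the cells of the Cd3g, Pdcd1, Ifitm1 and Xcr1 clusters. UMIs of the myeloid gene Lyz2, a second background marker for T cells, were found in 43.0% of Cd3g and 38.9% of Pdcd1 cells, near the Jaml share of the latter. Unthinned median depths were 8888 UMIs in the Cd3g, 23640.5 in the Pdcd1 and 13486 in the Siglech cluster. Cxadr had 1.66 ± 0.863 CPM in the Cd3g cluster, its highest among these 5 clusters, and was too sparse to be tested.

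**Figure D2:**
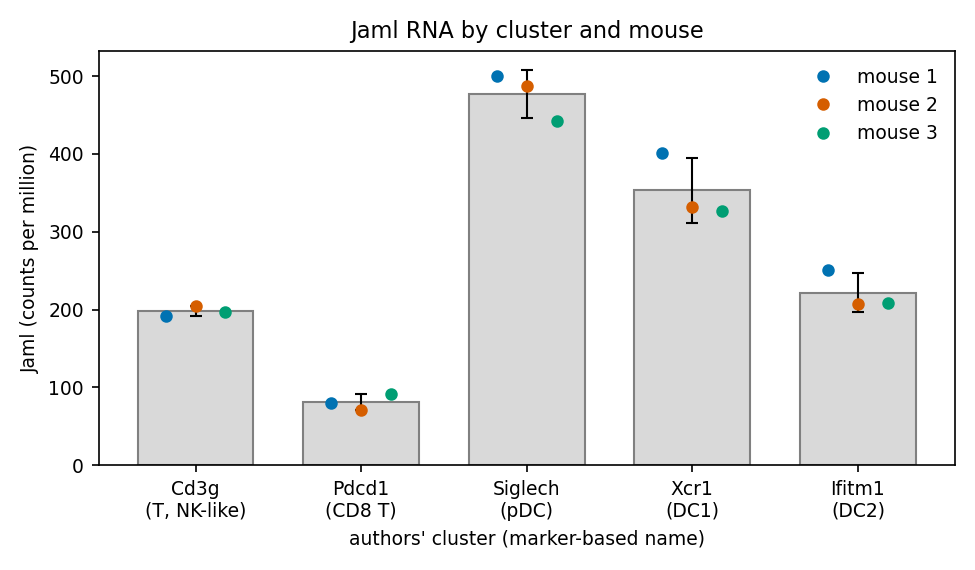
Jaml RNA in CPM (y axis) by 5 of the authors' 6 clusters (x axis, with a marker-based name); points are mice, bars the mean and error bars the SD (n = 3). All 3 mice show more Jaml in the Siglech cluster (mean 477 CPM) than in the Pdcd1 cluster (mean 81.2 CPM).

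The CD8 T cell-like subclusters formed groups of opposite character. One, inside the Cd3g cluster (subclusters 1, 7, 10 and 15; 1310 cells), carried transcripts of circulation and memory, and the cluster was led by S1pr1 (17.4-fold), which guides egress from tissue, Tcf7 (16.9-fold), Lef1, Txk and Sidt1. The other, called the Pdcd1 side (856 cells of subclusters 5, 8 and 14), carried checkpoint, effector and cell division transcripts, with G2 and M phase highest in subclusters 8 and 14. All but 3 of its cells lay in the Pdcd1 cluster, which was led by Igfbp7 (34.5-fold), Nrgn (33.7-fold), Nrn1, Rgs16 and Gldc. On the Pdcd1 side the checkpoint list was higher by 1.22 ± 0.34 (mean over members of log2 of CPM plus 1, SD over 3 mice) and cytotoxicity by 1.52 ± 0.50. S phase was higher by 2.51 ± 0.09, and G2 and M phase by 4.24 ± 0.38. The mean G2 and M level was 7.42 in subcluster 8 and 7.17 in subcluster 14 (2 mice), but 3.63 in subcluster 5, with 449 cells. On the Cd3g side that level was 2.43. Tissue residency was higher on the Pdcd1 side by 0.32 ± 0.11 (0.81 as a median over the list). Single residency genes went the other way, with more RNA on the Cd3g than on the Pdcd1 side of Itgae (14.4 ± 9.56 against 2.24 ± 1.10 CPM) and Cd69 (325 ± 23.8 against 152 ± 48.8 CPM). The Cd3g side was higher in the others, with differences of -1.39 ± 0.62 for recirculation and egress, -1.40 ± 1.09 for stem-like and memory and -1.88 ± 0.43 for interferon response. All 8 differences had one direction in 3 of 3 mice; no test was made, because the clusters were built on such genes. With clusters rebuilt without the list genes, the stem-like and memory difference was -0.62 ± 1.02, with the Pdcd1 side higher in 1 of 3 mice, and without mouse 1 it was -0.88. Subcluster 10 was led by Dapl1 (14.6-fold), Tdrp, Tcf7 (10.9-fold), Tmem108 and Satb1. The sides had unequal depth, with medians of 8863 and 23580 UMIs per cell, and mouse 3 gave 928 of the 1310 cells of the Cd3g side.

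**Figure D3:**
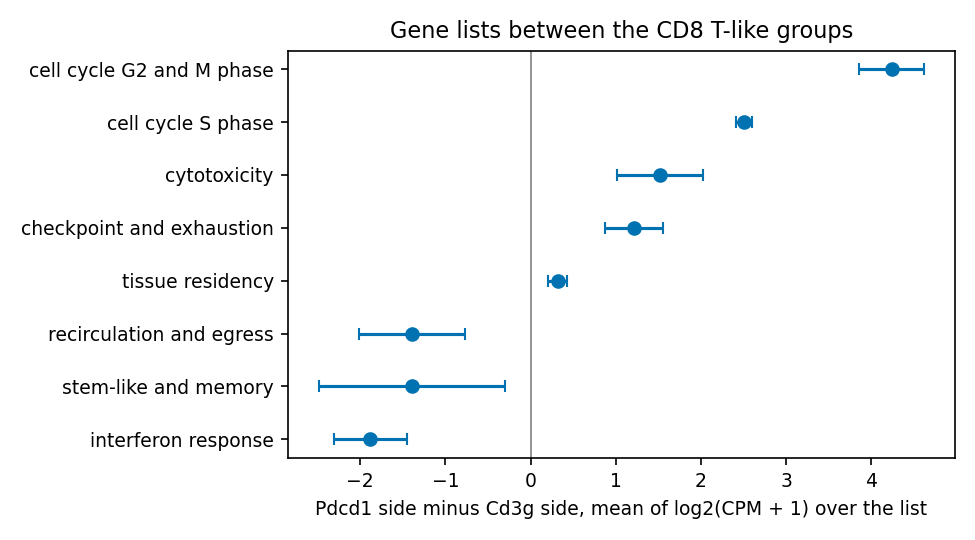
Difference between the Pdcd1 side and the Cd3g side of the CD8 T cell-like cells (x axis, mean over a list's members of log2 of CPM plus 1) for 8 gene lists (y axis); points are means over 3 mice and error bars the SD. G2 and M phase lies farthest right (4.24) and interferon response farthest left (-1.88). Within the Pdcd1 side the G2 and M level was higher in subclusters 8 and 14 (7.42 and 7.17) than in subcluster 5 (3.63).

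CD8-gate against CD4-gate cells asked how the lineages differ inside the sort. Within the T-cell clusters, CD8-gate cells had more RNA of genes such as Ccl3, Ccl4, Gzmb and Lag3, and CD4-gate cells had more of genes such as Cd40lg, Maf and Tmem176a. The comparison was matched neither for cluster nor for depth. Of the CD8-gate cells 800 of 2152 lay in the Pdcd1 cluster, against 7 of 59 CD4-gate cells. Median UMIs per cell in mice 1, 2 and 3 were 19253, 12129 and 9037 for CD8-gate and 7321, 5461 and 6359 for CD4-gate cells. The chemokine Ccl3 was higher in CD8-gate cells by 4.38 ± 0.31 on the log2 scale (SE, adjusted p = 1.8e-06; 690 ± 389 against 34.8 ± 21.4 CPM, SD, n = 3), and Ccl4 by 3.95 ± 0.44 (9.5e-05; 5.58 without mouse 1 and 3.20 without mouse 2). The cytotoxic protease gene Gzmb was higher by 2.54 ± 0.28 (9.5e-05; 781 ± 28.4 against 161 ± 107 CPM). Cd40lg, by which helper T cells activate antigen-presenting cells, was lower at -6.51 ± 0.72 (9.4e-05; 0.896 ± 0.826 against 78.6 ± 22.0 CPM), and so was Maf, a helper cell transcription factor, at -4.46 ± 0.40 (1.4e-05). Jaml did not differ past the threshold, at 135 ± 44.7 against 139 ± 67.5 CPM (log2 0.06 ± 0.33, adjusted p = 0.98, higher in 2 of 3 mice).

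By list, 12 of 21 cytotoxicity genes were higher in these CD8-gate cells (14, and 1 lower, adjusted over the list alone; median log2 1.999), among them the inhibitory receptor gene Klrc1 (3.62) and the chemokine gene Ccl5 (2.15). Camera gave this list an adjusted p of 9.2e-38, and 0.25 with an estimated correlation. Of 18 checkpoint genes, 9 were higher (9, adjusted over the list alone; median 1.46; adjusted p = 0.15 with an estimated correlation), including Lag3 (2.58), Nr4a2 (2.07), Pdcd1 (1.86) and Havcr2 (2.27; 2.07 and no longer past the threshold without mouse 1). Of 6 type 17 genes, 4 were lower (5, adjusted over the list alone; median -2.46; adjusted p = 0.15 with an estimated correlation), including Tmem176a (-2.97) and Rora (-2.07; -1.39 without mouse 1). Of 11 chemokine receptor genes, 3 were lower (7, and 3 higher, adjusted over the list alone; adjusted p = 0.53 with an estimated correlation). One was Ccr10 at -5.23 (-3.96 without mouse 1 and -6.04 without mouse 3). Of 16 natural killer receptor genes, 4 were higher (6, and 2 lower, adjusted over the list alone; adjusted p = 0.53 with an estimated correlation). Camera called 15 lists of 25 in this comparison; with an estimated correlation none had an adjusted p under 0.15, and fry called 0. Gzmf and Dapl1 had 0 UMIs in the CD4-gate cells and were at least 11.5-fold (3.72-fold without mouse 2) and 8.99-fold (5.90 to 6.22-fold with a mouse left out) higher in CD8-gate cells, against a floor of 5.50 CPM over the group. Other genes lower in CD8-gate cells were Trat1, a T cell receptor adaptor gene (-4.37), and Lmna (-3.44). In total 103 of 9495 genes passed, 53 higher and 50 lower, from 707, 366 and 1075 CD8-gate and 24, 11 and 24 CD4-gate cells per mouse. Without mouse 2 the count was 316. By DESeq2 29 genes were higher and 79 lower, and without the mouse block 6 and 17.

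Over all clusters, the gates took in other cell types. Of 155 CD4-gate cells, 76 lay in the plasmacytoid Siglech cluster, and of 2574 CD8-gate cells, 422 (16.4%) lay outside the T-cell clusters. The genes lower in CD8-gate cells were led by plasmacytoid genes such as Klk1 (log2 -5.11 ± 0.19, adjusted p = 3.0e-05; 18.6 ± 7.15 against 670 ± 111 CPM), and the signalling adaptor Tyrobp of myeloid and natural killer cells was at -2.15 ± 0.19. Higher in CD8-gate cells were Klrc1 (4.87 ± 0.25), Prf1, which encodes perforin (4.05 ± 0.34), Gzmb (3.92 ± 0.30), Pdcd1 (3.01 ± 0.19) and the cytotoxic granule gene Nkg7 (2.90 ± 0.14). Jaml was lower in CD8-gate cells, at 164 ± 29.5 against 337 ± 56.9 CPM (-0.94 ± 0.17, adjusted p = 0.0088). Cytotoxicity had 18 of 21 members higher (18, and 1 lower, adjusted over the list alone; adjusted p = 0.15 with an estimated correlation and 0.029 by fry), tissue residency 5 higher and 1 lower of 19 (6 and 1, adjusted over the list alone; adjusted p = 0.36 with an estimated correlation). Lipid handling had 7 of 15 members lower (7, adjusted over the list alone) and class II major histocompatibility genes 3 of 7 (6, adjusted over the list alone), each with an adjusted p of 0.36 with an estimated correlation. In total 1510 of 10587 genes passed, 578 higher and 932 lower. The count was 846 without mouse 1, 2269 without mouse 2, 794 without mouse 3 and 103 in the T-cell clusters alone.

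CD8-gate cells with an Itgae UMI were compared with matched cells without, since CD103 marks many tissue-resident memory T cells. Over all clusters, the cells with Itgae RNA were divided mainly between the type 1 dendritic cell-like and the T cell-like clusters. Of the 233 cells, 111 lay in the Xcr1 cluster and 103 in the T-cell clusters. In the Xcr1 cluster, 111 of the 117 CD8-gate cells and 89.6% of all cells had an Itgae UMI. With Itgae UMI, the chemokine receptor gene Xcr1 was higher by 6.92 ± 0.22 on the log2 scale (SE, adjusted p = 5.3e-07; 245 ± 102 against 2.11 ± 1.86 CPM, SD, n = 3; 7.58 without mouse 1), and Clec9a, a receptor for dead cells, by 5.09 ± 0.23 (3.2e-06). Class II antigen presentation genes were higher in 7 of 7 cases (7, adjusted over the list alone; median 2.20; adjusted p = 0.23 with an estimated correlation and 0.012 by fry), such as H2-Ab1 (2.41 ± 0.10) and H2-Eb1 (2.25 ± 0.06). Cytotoxicity genes were lower in 16 of 19 cases (17, adjusted over the list alone; adjusted p = 0.23 with an estimated correlation), with Gzmb at -2.09 ± 0.33, Ccl3 at -1.66 ± 0.15 and the natural killer receptor gene Klrd1 at -1.56 ± 0.09. Tissue residency had 2 members higher and 11 lower of 17 (2 and 11, adjusted over the list alone; adjusted p = 0.30 with an estimated correlation), including the retention receptor gene Cxcr6 at -0.98 ± 0.20 (adjusted p = 0.0073; 0.27 without cells that had lineage-conflicting UMIs). Checkpoint genes were lower in 12 and higher in 1 of 17 cases (13 and 2, adjusted over the list alone; adjusted p = 0.23 with an estimated correlation), with Pdcd1 at -1.74 ± 0.14. Jaml was higher with Itgae UMI by 1.53 ± 0.10 (1.8e-05; 297 ± 12.4 against 114 ± 11.2 CPM). In total 2238 of 8942 genes passed, 1317 higher and 921 lower. Without mouse 1 the count was 1051, and without cells that had lineage-conflicting UMIs it was 14 of 4664 genes. That removal left 20, 27 and 39 cells with an Itgae UMI in mice 1, 2 and 3, from 84, 60 and 89. Its rule takes out dendritic cell-like cells, since Lyz2 UMIs were found in 80.3% of Xcr1 cells after thinning.

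Inside the T-cell clusters, 103 cells with an Itgae UMI differed from 103 matched cells in 1 gene of 5286, and 204 genes had an unadjusted p under 0.05 (edgeR). The gene was Ifitm1, an interferon-induced membrane protein gene, higher by 3.09 ± 0.37 (adjusted p = 0.0041; 113 ± 9.94 against 13.7 ± 11.3 CPM). Of its 162 UMIs in cells with Itgae, 136 (84.0%) came from 3 cells, and 24.3% of cells with Itgae against 14.6% without had any. After thinning its log2 value was -0.0448. The call was lost without mouse 1 (0 genes, 191 with an unadjusted p under 0.05), without mouse 3 (0 and 174) and without the mouse block (0 and 56), and 9 genes passed without mouse 2; DESeq2 called 1. Jaml was at 198 ± 79.2 against 168 ± 87.7 CPM (log2 0.27 ± 0.18), Cd69 at -0.31 ± 0.13, Cxcr6 at -0.16 ± 0.11, Gzmb at -0.53 ± 0.30 and H2-Ab1 at 0.54 ± 0.18, each with an adjusted p of 1.0. Without mouse 2, Jaml was at -0.04 and Gzmb at 0.11. Camera called 4 lists of 24, glycolysis lower and interferon response, G2 and M phase and class II genes higher, with no member past the threshold (class II 3 higher and G2 and M phase 1 lower, adjusted over the list alone) and an adjusted p of 0.89 with an estimated correlation for each. An Itgae UMI was found in 5.71% of Cd3g and 3.50% of Pdcd1 cells, and in 1.44% of cells of the plasmacytoid Siglech cluster. In simulations that take the classes as true, the test recovered 55.8% of planted 2-fold changes at this size; background UMIs in the gate were not simulated.

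CD8-gate cells with a Jaml UMI were compared with matched cells without, to ask which transcripts go with Jaml. All cells were sorted as JAML-positive, so the cells without a Jaml UMI are not a JAML-negative class. A missing UMI can come from sampling: a Jaml UMI was found in 70.6% of Pdcd1 cluster cells unthinned and in 40.8% after thinning. Below, cells with or without Jaml are cells with or without a Jaml UMI. Over the T-cell clusters together, cells with a Jaml UMI carried more RNA of interferon-induced genes and of the chemokine gene Xcl1. They carried less of inducible heat shock genes and Ccl3. The pooled signs for Xcl1, Ccl3 and Hspa1a were those of the Pdcd1 cluster (1.28, -0.72 and -1.90, Hspa1a higher in 1 of 3 mice). Inside the Cd3g cluster Ccl3 was higher with Jaml (0.66), and Xcl1 (-0.28) and Hspa1a (0.18) did not pass the threshold. Isg15, a ubiquitin-like interferon-induced protein gene, was higher by 1.66 ± 0.08 on the log2 scale (SE, adjusted p = 2.1e-10; 195 ± 65.2 against 60.0 ± 21.5 CPM, SD, n = 3). The antiviral genes Slfn5 (1.62 ± 0.18, adjusted p = 2.5e-05), Mx1 (1.51 ± 0.16, 2.1e-05), Ifit3 (1.43 ± 0.11, 3.5e-07) and Ifit1 (1.39 ± 0.12, 4.8e-07) were higher as well. Xcl1, which attracts Xcr1-bearing dendritic cells, was higher by 1.47 ± 0.12 (4.8e-07; 754 ± 236 against 258 ± 30.5 CPM), with 35.9% of its UMIs in 3 cells, and Cxcl10 by 1.27 ± 0.20 (0.00092), with 53.1% in 3 cells. Lower with Jaml were the chaperone genes Hspa1a (-1.60 ± 0.17) and Hspa1b (-1.58 ± 0.21; -0.90 without mouse 3), Ccl3 (-0.88 ± 0.14, adjusted p = 0.00098), the mitochondrial protein gene Chchd10 (-0.73 ± 0.10), Cd55, which encodes a complement inhibitor (-0.65 ± 0.15; -0.49 without mouse 2 and -0.60 without mouse 3, both short of the threshold), and Rgs16 (-0.59 ± 0.10). In the cells without Jaml, 3 cells held 49.7% of the Hspa1a UMIs and 45.8% of the Hspa1b UMIs. The share of cells with a UMI did not follow these totals for Hspa1a (10.5% with Jaml against 9.18% without), Ccl3 (54.3% against 51.1%) and Cxcl10 (9.18% against 10.2%). Without cells that had lineage-conflicting UMIs, Hspa1a stood at 0.29 and Hspa1b at 0.20, and after thinning Xcl1 stood at -0.15.

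Of 25 interferon response genes measured, 23 were higher with Jaml (24, adjusted over the list alone; median log2 0.83). Camera gave an adjusted p of 2.5e-114 for this list, and 0.23 with an estimated correlation; fry gave 0.14. Isg15 was found in 51.6% of cells with Jaml against 37.9% without, Ifit3 in 38.4% against 23.8% and Ifi213, a DNA sensor family gene, in 48.0% against 33.1% (log2 0.95 ± 0.11). Heat stress genes were lower in 3 of 20 cases (7, adjusted over the list alone; adjusted p = 0.73 with an estimated correlation). S phase had 1 gene of 24 lower (5, adjusted over the list alone), the nucleotide enzyme gene Dut at -0.34 ± 0.06, and G2 and M phase 0 of 28 past the threshold (1, adjusted over the list alone); each had an adjusted p of 0.73 with an estimated correlation. Class II genes had 0 of 7 past the threshold (5, adjusted over the list alone; median 0.35; adjusted p = 0.73 with an estimated correlation), checkpoint genes 1 higher and 1 lower of 18 (1 and 1, adjusted over the list alone), and type 1 helper genes 2 higher of 12 (4 and 1 lower, adjusted over the list alone), also with an adjusted p of 0.73. Camera called 7 lists of 25, and fry 0. The inhibitory receptor genes Pdcd1 (-0.12, adjusted p = 0.66) and Havcr2 (-0.29, 0.26) and the residency genes Cxcr6 (0.12, 0.66) and Cd69 (0.15, 0.61) did not pass. Gzmb stood at 0.07 (0.91; 0.38 and past the threshold without mouse 2), Tcf7, a memory T cell factor gene, at -0.16 (0.82; -0.48 and past it without mouse 1) and Itgae at 0.97 (0.59; 2.22 and past it without mouse 3). In total 111 of 9472 genes passed, 83 higher and 28 lower, from 610 cells in each class (206, 100 and 304 per mouse). The count was 199 without mouse 1, 36 without cells that had lineage-conflicting UMIs, 26 by DESeq2 and 0 without the mouse block (150 with an unadjusted p under 0.05).

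**Figure D4:**
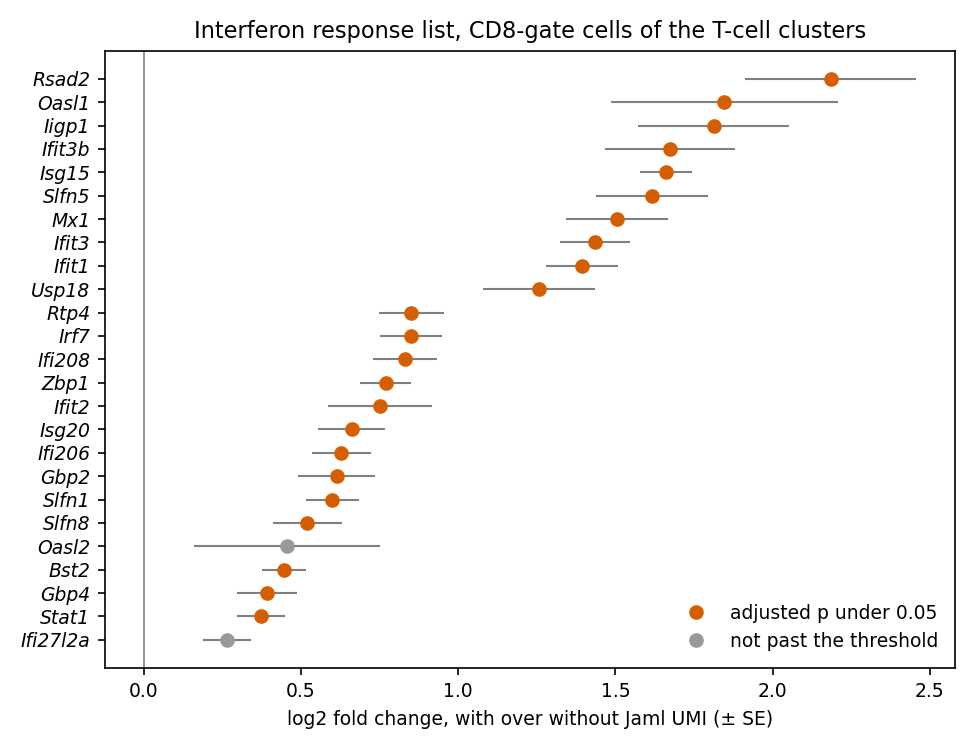
Log2 fold change (x axis, with SE) of each measured interferon response gene (y axis) in CD8-gate cells of the T-cell clusters with against without a Jaml UMI; colour marks the 23 of 25 genes past the threshold. All points lie right of 0, with a median of 0.83.

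Over all clusters, the comparison by Jaml UMI again brought in dendritic cell-like cells. Higher with Jaml were Xcr1 (5.30 ± 0.29, adjusted p = 4.9e-05; 4.52 without mouse 1), Itgae (3.51 ± 0.43, 0.0031; 2.70 without mouse 1 and 4.70 without mouse 3) and Wdfy4, which type 1 dendritic cells need for cross-presentation (3.49 ± 0.16). Class II genes were higher in 6 of 7 cases (7, adjusted over the list alone; median 1.22; adjusted p = 0.35 with an estimated correlation), such as H2-Ab1 (1.34 ± 0.19) and the invariant chain gene Cd74 (1.22 ± 0.17). Interferon response genes were higher in 13 of 26 cases (19, adjusted over the list alone; adjusted p = 0.35 with an estimated correlation), with Iigp1 at 1.76 ± 0.18, Bst2 at 0.91 ± 0.11 and Irf7 at 0.87 ± 0.11. Lower were the enkephalin precursor gene Penk (-3.14 ± 0.23), Hspa1a (-1.77 ± 0.11), Ccl3 (-1.51 ± 0.14) and Prf1 (-1.17 ± 0.16), with 10 of 20 cytotoxicity genes lower (10, adjusted over the list alone; adjusted p = 0.35 with an estimated correlation). In total 437 of 9906 genes passed, 313 higher and 124 lower, and 188 passed without mouse 1, 268 without mouse 3 and 26 without the mouse block.

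Inside the Cd3g cluster alone, the classes differed in genes of circulation, memory and effector function, and also in their make-up by subcluster. Dapl1 (-1.70 ± 0.27, adjusted p = 0.0043), the lymph node homing receptor gene Ccr7 (-1.69 ± 0.26, 0.0042) and the egress factor gene Klf2 (-0.51 ± 0.08, 0.0049) were lower with Jaml. Ccl3 (0.66 ± 0.14, 0.024), the calcium-binding protein gene S100a4 (0.51 ± 0.07, 0.0016), Cxcr6 (0.50 ± 0.08, 0.0049), Nkg7 (0.27 ± 0.05) and Ccl5 (0.26 ± 0.04) were higher. Isg15 (1.12 ± 0.20, 0.0091) and Mx1 (1.37 ± 0.28, 0.019) were higher in 2 of 3 mice and lower in 1, and fell short of the threshold without mouse 3 (0.89 and 1.30). Recirculation genes were lower in 4 of 13 cases (7, adjusted over the list alone) and tissue residency genes higher in 3 of 14 (3, adjusted over the list alone). Stem-like and memory genes were lower in 2 of 12 (5, adjusted over the list alone) and cytotoxicity genes higher in 3 of 18 (9, adjusted over the list alone), each of these 4 lists with an adjusted p of 0.44 with an estimated correlation. In total 90 of 5492 genes passed, 26 higher and 64 lower, but 0 passed without mouse 3 (399 with an unadjusted p under 0.05; edgeR), which gave most cells of the cluster, and 12 passed after thinning. Without the mouse block 0 passed (204 with an unadjusted p under 0.05). Higher and lower genes numbered 49 and 20 unmatched, 74 and 35 with a gate at 2 UMIs, 31 and 24 with another draw, and 13 and 46 by DESeq2. Without mouse 3 Dapl1 stood at -1.12, Ccr7 at -1.45 and Cxcr6 at 0.63. Subcluster 10, with 144 ± 19.2 CPM of Ccr7 against 18.1 ± 8.09 in subcluster 1, made up 15 of the 375 cells with Jaml and 46 of the 375 without, and natural killer-like subcluster 3 made up 41 and 52. Within subclusters 1 and 7 alone, 2 of 4447 genes passed, Isg15 (0.89 ± 0.14) and Hspa1b (-0.85 ± 0.15), and Cxcr6 (0.43) had an adjusted p of 0.67. Inside the Pdcd1 cluster, Isg15 (1.37 ± 0.17, 0.00017), Xcl1 (1.28 ± 0.11, 7.2e-07), the interferon regulatory factor gene Irf7 (1.01 ± 0.18, 0.015) and the mitotic cyclin gene Ccnb2 (0.80 ± 0.12, 0.0028) were higher, and Ccl3 was lower (-0.72 ± 0.11, 0.0036). There 46 of 7495 genes passed, 19 without mouse 1 or without mouse 3, 2 without cells that had lineage-conflicting UMIs, 3 by DESeq2 and 0 without the mouse block (311 with an unadjusted p under 0.05). Isg15 (1.36) and Irf7 (1.11) fell short of the threshold without mouse 1, and Irf7 (0.94) without mouse 3. Of 28 G2 and M phase genes 6 were higher (21, adjusted over the list alone), with a median of 0.56. Camera with an estimated correlation gave an adjusted p of 0.59. These classes were not matched for subcluster, and their make-up was not measured. A Jaml UMI was found in 67.5% of subcluster 5, 73.7% of subcluster 8 and 73.75% of subcluster 14 cells. Their G2 and M levels were 3.63, 7.42 and 7.17, so a difference in make-up was not separated from one within a subcluster.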

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

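Chosen only after the results were seen were the comparisons within single clusters with the test of their difference, the splits of the samples, and the tests of depth, of a few cells, of RNA content, of free plasmacytoid RNA in the Cd3g cluster, of the Cd8a to Cd8b1 ratio and of Cd8b1 in cells with Cd8a. The difference between Jaml-associated changes in the Pdcd1 and the Cd3g cluster was tested with an interaction term in edgeR over 7942 genes; 7 passed, and 491 had an unadjusted p under 0.05. The sign turned in Ccl3, which was higher with Jaml UMI in the Cd3g cluster (log2 0.66, in 3 of 3 mice) and lower in the Pdcd1 cluster (-0.72, higher in 0 of 3), a difference of -1.37 (adjusted p = 0.0016). Xcl1 differed by 1.57 (0.018), at -0.28 in the Cd3g cluster and 1.28 in the Pdcd1 cluster. Over both clusters, 3 cells held 35.9% of the Xcl1 UMIs of cells with Jaml, and after thinning Xcl1 stood at -0.15. Klf2 differed by 1.10 (0.026), at -0.51 and 0.58. S100a4 differed by -0.56 (0.030), at 0.51 and -0.06. Hspa1a differed by -2.18 (0.030), at 0.18 and -1.90, and in the Pdcd1 cluster it was higher with Jaml in 1 of 3 mice. The gene models Gm42418 (0.55, 0.0016) and AY036118 (1.01, 0.018) also differed. Both fall outside the naming rule and are named because of this test. The interaction was not refitted with a mouse left out; the Cd3g cluster alone had 0 genes past the threshold without mouse 3.

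In CD8-gate cells of the T-cell clusters, interferon response genes went with the presence of a Jaml UMI, with a median log2 of 0.83 over 25 genes. RNA of plasmacytoid cells carried along with Jaml is argued against. The share of such RNA gained was read as the median over the plasmacytoid marker genes outside the interferon list. That share would give at most 0.760% of the gain in any mouse. Total UMIs per cell as the whole cause is argued against by thinning inside the Cd3g cluster. The members still had a lower quartile of 0.387 and a median of 0.50 there. Thinned classes were not matched, but their unthinned median depths lay close there (11379, 9828.5 and 9362 UMIs with Jaml against 11232, 9897 and 9538 without). Inside the Pdcd1 cluster the values were 0.41 and 0.65. Cells with Jaml were shallower there before thinning, with medians of 21992, 20112.5 and 17057 against 25721.5, 29093 and 21338 UMIs. Thinning does not even out that difference between cells, so the Pdcd1 values cannot decide. Over both clusters the thinned median was 0.89, which also carries their unequal shares in the thinned classes. A few cells with very high counts are argued against by detection. Of the members, 76% (19 of 25) were found in a larger share of cells with Jaml in all 3 mice. Chance gives 12.5% for a single member, but members can move together, so that figure is no test of the list. The classes were not matched for cluster, so their mix of clusters was not held equal here. Leaving out subcluster 15, which interferon genes lead, left 54 genes past the threshold and a median of 0.62, so a shared interferon-exposed state of CD8 cells with more Jaml RNA may remain as a hypothesis; the design gives no group for it and no biological explanation was tested.

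Jaml CPM was lower in the Pdcd1 than in the Cd3g cluster in 3 of 3 mice. Cells of the Pdcd1 cluster held 2.16, 2.65 and 2.40 times as many UMIs in mice 1, 2 and 3, while Jaml UMIs per cell were nearly equal, with a ratio of 0.981 ± 0.114 (SD, n = 3), which is what a larger RNA content with an unchanged number of Jaml molecules would give. Free plasmacytoid RNA as the source of Jaml in the Cd3g cluster is argued against, since it would give at most 2.45% of that cluster's Jaml UMIs in any mouse. The lower CPM could therefore come from dilution by other transcripts, and the number of Jaml molecules per cell may not differ. A ratio within 1 SD of 1 over 3 mice cannot show that the numbers are equal. The Cd3g cluster also holds the natural killer-like subcluster 3, with 291 of its 456 cells in mouse 1, 122 of 341 in mouse 2 and 219 of 1147 in mouse 3. That mixture was not held equal. Surface JAML was sorted on, but no level per cell is among the values used here, and no biological explanation was tested.

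Of the 117 CD8-gate cells in the Xcr1 cluster, 111 had an Itgae UMI. So did 89.6% of all cells of that cluster, so the open question for the 111 is the source of their Cd3 and Cd8 UMIs. Pairs of a T cell and a dendritic cell under one barcode are argued against: these cells had a median of 1 Cd3 UMI against 43 in CD8-gate cells of the T-cell clusters, and the highest median of a mouse was 4.44% of the level there. Free T cell RNA in dendritic cells that carry Cd8a, as some type 1 dendritic cells do, was predicted to leave Cd8b1 in at most 25% of these cells, and 49.5% had it. That bound was wrong by design, since the gate itself asks for Cd8a or Cd8b1 and let in 31 cells by Cd8b1 alone. Among the 80 cells with a Cd8a UMI, 30% had Cd8b1 (95% interval 20.3 to 41.3%), which does not settle it, and the share of Xcr1 cells with a Cd3 UMI after thinning, 21.4 ± 1.68%, lay between those of the Siglech (19.7 ± 2.02%) and Ifitm1 (21.7 ± 0.747%) clusters. Free T cell RNA alone is argued against by the ratio of Cd8a to Cd8b1 UMIs, 1.998 ± 0.810 in the Xcr1 cluster against 0.363 ± 0.0705 in the Siglech and 0.955 ± 0.0857 in the Ifitm1 cluster. Their own Cd8a with free Cd8b1 and Cd3 RNA could therefore still be the source, and no biological explanation was tested.

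For comparisons of 3 against 3 sums there are 10 splits, too few for a share under 0.05. With the mouse as a block, the 6 splits that part 1 of the 3 pairs of a mouse rest on the real difference within that mouse, so the 3 others that part all 3 pairs are given beside the highest of all other splits. The real split gave 1510 genes for CD8 against CD4 gates, 2238 for Itgae and 437 for Jaml, each with 0 as the highest of all others. In the T-cell clusters it gave 103 against 12 for CD8 against CD4 gates and 111 against 2 for Jaml, and these are also the highest with all pairs parted. In each of these only 1 split, the real one, gave as many. The same held inside the Cd3g cluster (90 against 22, which parts all pairs), the Pdcd1 cluster (46 against 29, and 0 with all pairs parted) and subcluster 4 (22 against 13, and 2 with all pairs parted). For Itgae in the T-cell clusters, 6 of 10 splits gave as many as the real 1 gene, and the highest other gave 16, or 4 with all pairs parted. In subcluster 3, 4 of 10 gave at least the real 7 genes, and the highest other gave 15, or 7 with all pairs parted.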

How the results depend on the processing

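Chosen only after the data were seen were the restriction to the T-cell clusters, all values within them, and the comparisons inside single clusters or subclusters. The choice that moved gene counts most differed between comparisons, and RLE scaling moved them little: the 8 genes given values for CD8 against CD4 gates over all clusters kept their calls in 10 of 10 alternatives (the stricter cell filter among them removed 1 cell and tests nothing), and RLE factors gave 1517, 104 and 2302 genes where TMM gave 1510, 103 and 2238. Of the 15 called genes given values for Jaml in the T-cell clusters, all lost their call without the block, 8 kept it under DESeq2 and 6 without conflicting cells. Not run were the comparison of regulatory cells (no Foxp3 row) and lineage by cluster (no CD4 cluster). A gate at 2 UMIs left out mouse 1 (3 cells) for Itgae in the T-cell clusters. The self-test recovered few 1.5-fold changes for CD4-gate cells (4.6%, among the 2677 of 9501 genes drawn from), so small changes there would mostly be missed. Whether depth, cell number or dispersion sets this was not tested. Unless a value shows it, the cause was not tested.

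For CD8 against CD4 gates (1510 genes), the count was 699 at a threshold of 0.01, 2676 without conflicting cells, 103 in the T-cell clusters, and 794 to 2269 with a mouse left out (without mouse 3, without mouse 2). In the T-cell clusters (103 genes) it was 253 without the filter, 23 without the block, 47 at 0.01, 177 without conflicting cells, and 99 to 316 (without mouse 3, without mouse 2). For Itgae (2238 genes) it was 1058 by DESeq2, 1285 at 0.01, 14 without conflicting cells, 96 after thinning, 1 in the T-cell clusters, and 1051 to 1756 (without mouse 1, without mouse 3). In the T-cell clusters (1 gene) it was 22 without the filter, 0 without the block, 0 without conflicting cells, 0 with a gate at 2 UMIs, 11 unmatched, 3 after thinning, 3 with another draw, 2 in the Cd3g cluster alone, and 0 to 9 (without mouse 1, without mouse 2). For Jaml (437 genes) it was 184 by DESeq2, 26 without the block, 138 at 0.01, 731 unmatched, 111 in the T-cell clusters, and 188 to 388 (without mouse 1, without mouse 2). In the T-cell clusters (111 genes) it was 26 by DESeq2, 0 without the block, 59 at 0.01, 36 without conflicting cells, 303 with a gate at 2 UMIs, 197 after thinning, 54 without subcluster 15, 2 in subclusters 1 and 7 alone, 46 in the Pdcd1 cluster alone, and 105 to 199 (without mouse 3, without mouse 1). The stricter threshold lowers a count by construction. Removal of conflicting cells also left fewer cells to compare. In the T-cell clusters, 609 of 2152 CD8-gate cells had at least 2 UMIs of Cd79a, Lyz2 or C1qa. Over all clusters, the same rule takes out dendritic cell-like cells. How much of those shifts this explains, and the cause of the others, was not tested.

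Camera calls numbered 12, 15, 17, 4, 10 and 7 in these comparisons in the order above; with an estimated correlation there were 0 in each, and fry gave 3, 0, 10, 0, 0 and 0. Without the block camera called 1 list for Itgae in the T-cell clusters. The interferon list in the Jaml comparison there (median 0.83) had an adjusted p of 0.23 with an estimated correlation and 0.14 by fry, and medians of 0.62 to 0.89 over the alternatives, among them 0.76 without conflicting cells and 0.69 unmatched. The Xcr1 share was 7.68% in clusters rebuilt at resolutions of 0.4 and 1.2, and 7.52 to 7.53% with a mouse left out. For CD8 groups, the residency difference was 0.81 as a median and the S phase difference 1.99 in rebuilt clusters.

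Signs turned as follows, and the cause was not tested. Without conflicting cells, Cxcr6 stood at 0.27 for Itgae over all clusters; in the T-cell clusters Cxcr6 at 0.0142 and H2-Ab1 at -0.19 for Itgae, and Hspa1a at 0.29, Hspa1b at 0.20, Pdcd1 at 0.0347 and Cd69 at -0.000955 for Jaml. With a gate at 2 UMIs for Itgae there, Cxcr6 stood at 0.67, H2-Ab1 at -0.13 and Gzmb at 0.35. Unmatched, Cd69 stood at 0.10 and Cxcr6 at 0.0525 for Itgae, and Gzmb at -0.0223 for Jaml. After thinning, Ifitm1 stood at -0.0448, Cd69 at 0.20 and Cxcr6 at 0.17 for Itgae, and Xcl1 at -0.15, Gzmb at -0.0853 and Tcf7 at 0.10 for Jaml. With another draw Gzmb stood at -0.17 for Jaml. With a mouse left out, Jaml ranged from -0.39 to 0.79 for CD8 against CD4 and from -0.0438 to 0.54 for Itgae, Gzmb from -1.06 to 0.11 for Itgae and from -0.18 to 0.38 for Jaml, Cxcr6 from -0.0162 to 0.20 and Tcf7 from -0.48 to 0.27 for Jaml.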

Other observations

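The comparisons of cells with and without a Jaml UMI inside subcluster 4 and subcluster 3 were chosen after the data were seen. In the type 2 dendritic cell-like subcluster 4, 22 of 3831 genes passed, from only 19, 10 and 20 cells per class in mice 1, 2 and 3. A Jaml UMI was found in 90.6% of the subcluster's cells, so the cells without are a small remainder. How many cells hold the UMIs of each gene was not measured here. The complement gene C1qb (-3.49 ± 0.36, adjusted p = 0.00032; -4.13 without mouse 3) and the chemokine genes Ccl3 (-3.73 ± 0.40, 0.00032) and Ccl4 (-3.21 ± 0.23, 6.9e-06) were lower with Jaml, and the protease inhibitor gene Cst3 was higher (0.95 ± 0.11, 0.00066). The count was 98 without mouse 1, 4 without mouse 2, 47 without mouse 3 and 6 without the mouse block, where 2 of these 4 genes fell short of the threshold. In the natural killer-like subcluster 3, 7 of 6610 genes passed, among them Cxcl10 (1.46 ± 0.25, 0.0096) and Isg15 (0.95 ± 0.19, 0.034), both higher with Jaml, and the receptor gene Klra4, which was lower (-1.90 ± 0.30, 0.0061). The count was 12 without mouse 1, 37 without mouse 2, 2 without mouse 3, 2 without the mouse block and 0 by DESeq2 (30 with an unadjusted p under 0.05); Isg15 (0.91 and 0.72) and Cxcl10 (0.98 and 1.49) fell short of the threshold without mouse 1 and without mouse 3, and Klra4 (-1.22) without mouse 3.

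Subcluster 12, migratory dendritic cell-like and led by the actin-bundling gene Fscn1 (631-fold), the chemokine gene Ccl22 (202-fold), Cacnb3, Nudt17 and Il4i1, had 159 ± 24.7 CPM of Jaml (SD, n = 3), against 231 ± 22.2 in subcluster 4. The cycling dendritic cell-like subcluster 11, with 82 cells of the Xcr1, 44 of the Ifitm1 and 3 of the Pdcd1 cluster, had 332 ± 52.7 CPM and the natural killer-like subcluster 3 had 149 ± 38.0. Subcluster 15, 44 cells led by the interferon-induced genes Ifit3b (43.3-fold), Ifit3 (31.4-fold) and Ifit1 (27.6-fold), had 651 ± 102 CPM in the 2 mice with at least 10 cells. Subcluster 13 of the Siglech cluster, led by Apod (83.1-fold), Cyp7b1, Pi16, Alox5 and Calm4, had 444 ± 57.2 CPM.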
